A study of Gallus gallus with 28 samples.

How the data were processed

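The series measured gene expression by RNA sequencing in basilar papillae of the chicken. Per the labels, papillae were dissected, exposed to streptomycin for 24 h and left to recover, total RNA was taken with Trizol, and libraries were made with Illumina protocols. The deposited table holds 1 value in RPKM (reads per kilobase of gene per M reads, computed by the authors) for each of 17684 features and each library, with the number of alignments of each library. TopHat 1.4.0 and Partek 6.6 are named in the processing notes of the submitters with no roles, and the genome build and annotation are not given in the sources used here, so no positions are reported. The table has 32 columns, of which 4 match no sample of the series and were not used here, although their headings name second samples of the 4 groups with 1 sample. The series text speaks of more samples than the 28, and those were not analysed here. Libraries held 16.48 to 38.17 M alignments (median 19.85 M). Counts per gene are not in the table, so no counting intervals are given.

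Samples were grouped by treatment and time from their titles. Features with RPKM of at least 1 in at least 2 samples were kept, 12195 in all, and log2(RPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided moderated test). Genes with a Benjamini-Hochberg adjusted p under 0.05 over the features tested are said to pass. The comparison over all times used time and treatment as additive terms (19 residual degrees of freedom). The others were contrasts in a model with 1 mean for each of the 16 groups (12 residual degrees of freedom): treated minus control averaged over 0, 24 and 48 h, over 120, 144 and 168 h, the difference of these, each single time, and late minus early in controls. A group with 1 sample is assumed to vary like the others. Late minus early in treated samples was added after seeing the data. Comparisons, gene lists, alternatives and the rule for naming genes were otherwise fixed before the data were examined.

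Gene names are those of the table, where 11718 of the features carry a symbol found in the reference gene table and 5483 a locus or accession identifier. There were 32 gene lists with 1028 members, of which 790 matched a feature, 16 of them by a synonym. They cover hair cell function, early hair cells, supporting cells, Notch, DNA replication (S phase), mitosis (G2 and M), p53 and apoptosis, heat shock, the unfolded protein and integrated stress response, immediate early genes, inflammation, JAK/STAT, interferon, FGF, Wnt, BMP and TGF-beta, matrix remodelling, mesenchyme, cartilage, neurons, glia, leukocytes, erythrocytes, endothelium, muscle, ion-transporting epithelium, melanocytes, mitochondrially encoded genes, nuclear oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, and ribosomal proteins. Some genes stand in more than 1 list. Counts are of measured members. Lists with at least 5 measured members were tested with camera from limma at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Of 181 list calls with the preset value, 16 held with the estimated correlation, those of hair cell function at 0 to 48 h, at 120 to 168 h, for the difference, in controls and at each single time among them, with the neuron list at 0 to 48 h. For every list that passed, the median, the mean and the test had the same sign.

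Named genes are, for each comparison over several times, the 8 largest rises and 8 largest falls among genes that passed, had a symbol and a mean RPKM of at least 1 in an arm, and differed the same way at 6 or more of the 8 times (all times) or at all 3 times (0 to 48 h and 120 to 168 h). For single times the 2 largest each way were taken. From each list up to 3 members per direction were eligible, and 12 genes were followed whether they passed or not. Not all eligible members are named, and 1 gene is not reported here.

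Alternatives were a pseudocount of 0.1, no filter, no intensity trend, median-of-ratios rescaling, a replicate block by sample number across all samples or within each time, only the samples compared in the fit, narrower windows (0 and 24 h, 144 and 168 h), an equal-weight mean of the 8 times, and leaving out each library in turn. Added after seeing the data were fits without 72, 96 and 120 h and without 24 and 168 h. Differences between samples 1 and 2 of a time correlated between the arms across genes at 0.31, 0.29, 0.11, 0.48 and 0.41 (0, 24, 48, 144 and 168 h). The replicate block was among the alternatives fixed beforehand.

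Simulated data held 67 genes changed 2-fold among a similar number of features. The fit over all times recovered 100% of them, 0 to 48 h 98.5%, 120 to 168 h 94%, the difference 86.6% and controls 94%. Single times gave 31.3% (96 h) to 82.1% (144 h). At 1.5-fold the first 5 gave 91%, 82.1%, 68.7%, 35.8% and 65.7%. Unchanged genes were 7 of 201 (all times) to 19 of 206 (0 to 48 h) of their calls.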

Results

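The series followed the chicken basilar papilla, the hearing epithelium of the bird, after treatment with streptomycin, an aminoglycoside antibiotic that kills hair cells. Unlike mammals, birds replace lost auditory hair cells, and the title of the series names hair cell regeneration as its subject. RNA sequencing values from 28 samples were used, 15 treated and 13 control. They fell on 8 time points from 0 to 168 h, 24 h apart, and so into 16 groups. Of these, 12 groups held 2 samples and 4 held 1 (controls at 72, 96 and 120 h, treated at 96 h). Libraries held 16.48 to 38.17 M alignments (median 19.85 M). At 0 to 48 h depth was 22.8 M ± 3.7 (SD, n = 6) in treated and 24.7 M ± 6.4 (SD, n = 6) in control samples. At 120 to 168 h it was 18.6 M ± 2.1 (SD, n = 6) and 18 M ± 1.1 (SD, n = 5). Levels are given in RPKM as mean ± SD. Differences are given as the fitted log2 difference ± standard error on the scale of log2(RPKM + 1), which understates folds of genes with low values. Limma p-values measure only the spread between these samples. Those of camera compare genes and rest on the inter-gene correlation used. The labels do not say whether samples of a group came from separate animals or cultures.

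The first principal component held 39.5% of the variance and the second 19.9%. Replicate libraries of a group correlated across genes with r between 0.959 and 0.987, where genes are not independent replicates. The share of RPKM in mitochondrially encoded genes ranged from 1.48% to 4.67% in treated libraries and from 2.64% to 6.66% in control libraries. Its mean was lower in treated samples at each of the 8 times.

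**Figure D1:**
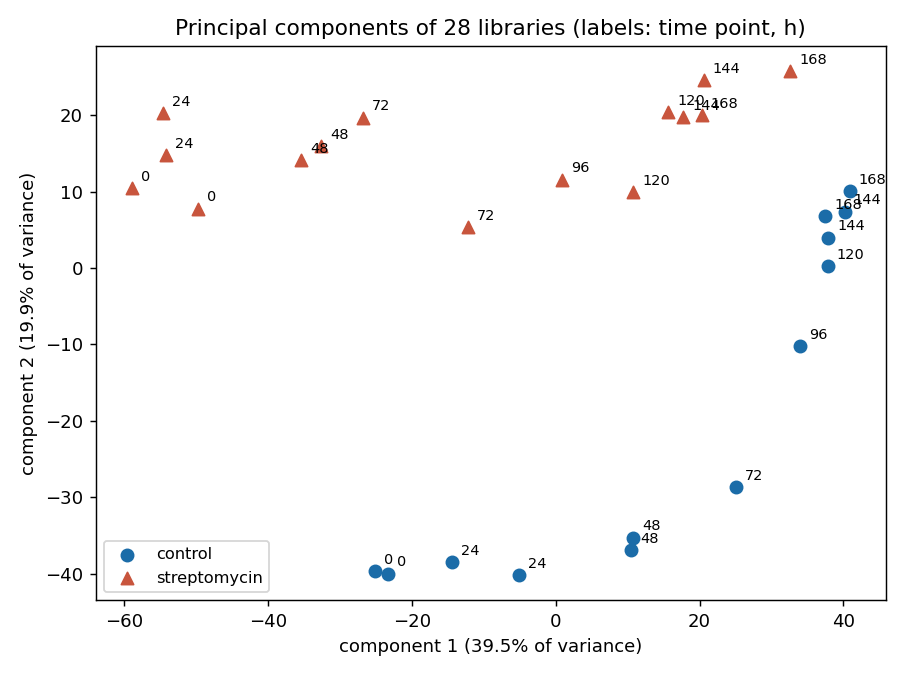
Principal component 1 (39.5% of variance, horizontal axis) and 2 (19.9%, vertical axis) of log2(RPKM + 1) in the 28 libraries, each point 1 library. Colour marks treated or control samples, and the number beside a point is the time in hours.

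The comparison over all times asked which genes differed between treated and control papillae when each time was set against its own control (n = 15 treated and 13 control). Genes of hair cells were among the largest falls. OCM2, which encodes a calcium-binding protein of the oncomodulin family, stood at 6.47 ± 7.29 against 373 ± 255 RPKM (-5.63 ± 0.24, limma adjusted p = 3.72e-14). The mechanotransduction channel gene TMC2 stood at 0.135 ± 0.0897 against 24.4 ± 16.4 RPKM (-4.17 ± 0.23). OTOF, the otoferlin gene needed for synaptic vesicle release, stood at 3.09 ± 1.92 against 58.6 ± 36.1 RPKM (-3.75 ± 0.33, adjusted p = 4.68e-09). MYO7A, a motor gene of the hair bundle, stood at 1.91 ± 1.05 against 17.8 ± 8.73 RPKM (-2.67 ± 0.22, adjusted p = 1.32e-09). Further large falls were FAM70B -4.81 ± 0.22, SNCG -4.22 ± 0.23, TMPRSS3 -3.72 ± 0.17, SS2 -3.68 ± 0.20 and NELL1 -3.66 ± 0.16. The largest rise was that of the water channel gene AQP5, at 22.4 ± 35 against 1.5 ± 1.13 RPKM (2.29 ± 0.38, adjusted p = 4.35e-05). GJB6, a gap junction gene of supporting cells, stood at 260.2 ± 209 against 62.5 ± 45.4 RPKM (1.87 ± 0.32, adjusted p = 7.34e-05). Other large rises were NOXO1 2.06 ± 0.37, PLEKHG1 1.8 ± 0.28, CBLN4 1.78 ± 0.25, PLAU 1.62 ± 0.16, C2H8orf22 1.58 ± 0.18 and MSMB 1.58 ± 0.23. Each of these falls was seen in 15 of 15 treated libraries against the control mean of the same time, and each rise in at least 14. OCM2 belongs to a family of similar copies, so the source of its reads is uncertain, and the strand of the libraries was not stated.

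Genes of the hair bundle, mechanotransduction and the ribbon synapse fell as a group, as 0 rose and 37 fell of 42 (0 and 39 adjusted over the list alone). Their median was -1.8 (camera adjusted p = 1.22e-28, adjusted p = 0.117 with an estimated correlation). SLC17A8, the vesicular glutamate transporter gene of hair cells, was among them (-3.63 ± 0.18). Of the transcription factors and signals of newly forming hair cells, 2 rose and 4 fell of 8 (2 and 4 adjusted over the list alone). The list median was -0.81 (camera adjusted p = 0.0337, adjusted p = 0.393 with an estimated correlation). GFI1 (-2.75 ± 0.19), LHX3 (-2.53 ± 0.24) and POU4F3 (-2.12 ± 0.27), transcription factors of differentiating hair cells, fell. ATOH1, the transcription factor that starts hair cell formation, rose to 8.62 ± 6.42 against 3.14 ± 3.61 RPKM (1.21 ± 0.25, adjusted p = 0.000585). It was higher in 12 of 15 treated libraries.

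Among supporting cell and prosensory genes, 10 rose and 4 fell of 16 (10 and 4 adjusted over the list alone). The median was 0.62 (camera adjusted p = 0.0258, adjusted p = 0.451 with an estimated correlation). SOX2, a transcription factor of prosensory and supporting cells, stood at 48.9 ± 23.3 against 23.5 ± 10.9 RPKM (1.02 ± 0.15, adjusted p = 8.46e-06). BMP4 (-1.37 ± 0.19) fell. The Notch list did not pass, with 4 higher and 2 lower of 15 (5 and 2 adjusted over the list alone, camera adjusted p = 0.365). Within it the receptor gene NOTCH1 (0.93 ± 0.18), its target HEY2 (0.72 ± 0.10) and the modifier gene LFNG (0.56 ± 0.16) rose.

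Among leukocyte markers 1 rose and 15 fell of 24 (2 and 16 adjusted over the list alone). The median was -0.39 (camera adjusted p = 0.000116, adjusted p = 0.451 with an estimated correlation). The antigen presentation gene CD74 stood at 21.9 ± 14.2 against 62.8 ± 34.6 RPKM (-1.53 ± 0.17). Among neuron markers 0 rose and 8 fell of 12 (0 and 9 adjusted over the list alone). Members had a median of -0.53 (camera adjusted p = 0.000110, adjusted p = 0.117 with an estimated correlation). The neurofilament genes NEFM (-2.4 ± 0.26) and NEFL (-1.39 ± 0.14) fell. In the mesenchyme list 2 rose and 14 fell of 23 (2 and 16 adjusted over the list alone). Their median was -0.53 (camera adjusted p = 0.00246, adjusted p = 0.459 with an estimated correlation). For matrix remodelling 1 rose and 15 fell of 31 (1 and 15 adjusted over the list alone). The set had median -0.33 (camera adjusted p = 0.00246, adjusted p = 0.259 with an estimated correlation). Falls included SPP1 (-2.2 ± 0.19) and FN1 (-1.6 ± 0.20), which encode osteopontin and fibronectin. Of cartilage markers 2 rose and 6 fell of 13 (2 and 8 adjusted over the list alone). The median was -0.40 (camera adjusted p = 0.0315, adjusted p = 0.259 with an estimated correlation).

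BMP and TGF-beta genes were lower, as 5 rose and 17 fell of 34 (5 and 17 adjusted over the list alone). Their median was -0.26 (camera adjusted p = 0.00931, adjusted p = 0.141 with an estimated correlation). In the inflammation list 3 rose and 11 fell of 27 (3 and 14 adjusted over the list alone). Across the list the median was -0.27 (camera adjusted p = 0.0337, adjusted p = 0.451 with an estimated correlation). The chemokine gene CXCL14 (-2.69 ± 0.23) and the protease gene MMP9 (-1.52 ± 0.24) fell. Of genes of the ion-transporting duct epithelium 1 rose and 9 fell of 15 (1 and 9 adjusted over the list alone). The median was -0.41 (camera adjusted p = 0.00246, adjusted p = 0.141 with an estimated correlation). In cholesterol synthesis 0 rose and 16 fell of 19 (0 and 16 adjusted over the list alone). The median was -0.60 (camera adjusted p = 0.000116, adjusted p = 0.451 with an estimated correlation). In glycolysis and hypoxia 1 rose and 12 fell of 30 (1 and 13 adjusted over the list alone). The median over members was -0.27 (camera adjusted p = 0.0217, adjusted p = 0.690 with an estimated correlation). Mitochondrially encoded genes gave 1 direction, as 0 rose and 5 fell of 5 (0 and 5 adjusted over the list alone). Their median was -0.83 (camera adjusted p = 0.000110, adjusted p = 0.141 with an estimated correlation). Of ribosomal protein genes 0 rose and 10 fell of 58 (0 and 0 adjusted over the list alone). The median was -0.21 (camera adjusted p = 0.00246, adjusted p = 0.690 with an estimated correlation).

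The other lists did not pass over all times. DNA replication genes gave 4 higher and 1 lower of 28 (3 and 1 adjusted over the list alone, camera adjusted p = 0.354). Mitosis genes gave 0 higher and 3 lower of 31 (0 and 0 adjusted over the list alone, camera adjusted p = 0.0789). The p53 and apoptosis list gave 9 higher and 5 lower of 31 (12 and 5 adjusted over the list alone, camera adjusted p = 0.199). Heat shock genes gave 8 higher and 2 lower of 20 (8 and 2 adjusted over the list alone, camera adjusted p = 0.0655). The unfolded protein and integrated stress response list gave 2 higher and 8 lower of 25 (2 and 8 adjusted over the list alone, camera adjusted p = 0.212). Immediate early genes gave 6 higher and 1 lower of 15 (6 and 2 adjusted over the list alone, camera adjusted p = 0.150). JAK/STAT genes gave 2 higher and 3 lower of 18 (1 and 2 adjusted over the list alone, camera adjusted p = 0.387). Interferon genes gave 5 higher and 2 lower of 21 (4 and 2 adjusted over the list alone, camera adjusted p = 0.149). FGF genes gave 5 higher and 5 lower of 23 (5 and 6 adjusted over the list alone, camera adjusted p = 0.849). Wnt genes gave 8 higher and 6 lower of 32 (8 and 6 adjusted over the list alone, camera adjusted p = 0.637). Glia markers gave 1 higher and 6 lower of 12 (1 and 6 adjusted over the list alone, camera adjusted p = 0.0549). Erythrocyte markers gave 0 higher and 1 lower of 8 (0 and 1 adjusted over the list alone, camera adjusted p = 0.133). Endothelial markers gave 2 higher and 4 lower of 11 (2 and 4 adjusted over the list alone, camera adjusted p = 0.309). Muscle markers gave 2 higher and 5 lower of 10 (2 and 5 adjusted over the list alone, camera adjusted p = 0.150). Melanocyte markers gave 0 higher and 4 lower of 8 (0 and 4 adjusted over the list alone, camera adjusted p = 0.0556). Nuclear genes of oxidative phosphorylation gave 4 higher and 4 lower of 56 (4 and 2 adjusted over the list alone, camera adjusted p = 0.934).

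In all, 5111 of 12195 tested genes passed over all times, 2464 higher and 2647 lower in treated samples. Of those changed at least 2-fold, 37 were higher and 323 lower. Without 72, 96 and 120 h, the times with a lone control sample (chosen after seeing the data), the calls of the supporting cell list (adjusted p = 0.0716), the inflammation list (adjusted p = 0.0822) and TECTA, a tectorial membrane gene (1.37 ± 0.38, adjusted p = 0.00606, then 0.94, adjusted p = 0.0966), ended. The early hair cell list lost its call with rescaling (adjusted p = 0.0506), no filter (adjusted p = 0.106), blocks within each time (adjusted p = 0.0626) and without treated 168 h replicate 2 (adjusted p = 0.0506), and the inflammation list without the control at 72 h (adjusted p = 0.0638).

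At 0 to 48 h, hair cell genes fell to a small part of their control level (n = 6 treated and 6 control). OTOF stood at 1.44 ± 0.462 against 81.6 ± 18.5 RPKM (-5.07 ± 0.21, limma adjusted p = 2.91e-12). MYO7A stood at 1.06 ± 0.475 against 22.1 ± 6.42 RPKM (-3.47 ± 0.12, adjusted p = 3.37e-13) and OCM2 at 11 ± 10.2 against 542 ± 182 (-5.85 ± 0.21). Other large falls were FAM70B -5.61 ± 0.11, KCNAB1 -4.96 ± 0.13, TMC2 -4.84 ± 0.10, SNCG -4.84 ± 0.16, SCG3 -4.58 ± 0.12 and SLC7A14 -4.3 ± 0.18. Some genes of supporting cells rose. GJB6 reached 481 ± 139 against 75.2 ± 65.4 RPKM (3.03 ± 0.19, adjusted p = 7.19e-10). SOX2 reached 72.6 ± 14.6 against 27.7 ± 15.2 RPKM (1.5 ± 0.12, adjusted p = 1.64e-08). GATA3 reached 45.9 ± 10.5 against 16.6 ± 13 RPKM (1.68 ± 0.15). AQP5 rose most, to 50.0 ± 43.4 against 2.12 ± 1.33 RPKM (3.72 ± 0.31, adjusted p = 4.65e-08). After it and GJB6 came PLEKHG1 2.68 ± 0.17, NOXO1 2.65 ± 0.33, CBLN4 2.26 ± 0.22, TRPM3 2.09 ± 0.17, DUSP16 2.03 ± 0.14 and ABHD6 1.95 ± 0.19. The 8 largest rises and 8 largest falls were each seen in 6 of 6 treated libraries.

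Of the hair cell function list, 1 rose and 37 fell of 42 (1 and 38 adjusted over the list alone). The median was -2.23 (camera adjusted p = 2.53e-28, adjusted p = 0.00611 with an estimated correlation). Of the early hair cell list, 2 rose and 4 fell of 8 (2 and 4 adjusted over the list alone). The median was -1.08 (camera adjusted p = 0.00634, adjusted p = 0.383 with an estimated correlation). It held falls of GFI1 (-3.39 ± 0.13), LHX3 (-3.33 ± 0.18) and POU4F3 (-3.33 ± 0.13). Of the supporting cell list, 10 rose and 3 fell of 16 (10 and 3 adjusted over the list alone). Their median was 0.67 (camera adjusted p = 0.00592, adjusted p = 0.318 with an estimated correlation). EYA1 was among the rises (1.61 ± 0.10) and BMP4 among the falls (-2.15 ± 0.14). Notch genes gave 8 higher and 3 lower of 15 (8 and 3 adjusted over the list alone, camera adjusted p = 0.277). Rises included NOTCH1 1.69 ± 0.09, LFNG 1.13 ± 0.13 and HEY2 0.92 ± 0.14.

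DNA replication genes rose early, as 16 rose and 0 fell of 28 (16 and 0 adjusted over the list alone). The list median was 0.32 (camera adjusted p = 0.00490, adjusted p = 0.442 with an estimated correlation). The rise came from 24 and 48 h and not from 0 h, as given with the single times. One example was the cyclin gene CCNE1 (0.55 ± 0.13). Mitosis genes gave 0 higher and 0 lower of 31 (0 and 0 adjusted over the list alone, camera adjusted p = 0.704), with 0 members at an unadjusted p under 0.05, while calls at single times had both signs. Immediate early genes rose, as 9 rose and 1 fell of 15 (9 and 1 adjusted over the list alone). The median was 0.73 (camera adjusted p = 0.00592, adjusted p = 0.442 with an estimated correlation). EGR1 was among them (1.32 ± 0.24). Of interferon genes, 12 rose and 1 fell of 21 (12 and 1 adjusted over the list alone). The median was 0.39 (camera adjusted p = 0.00522, adjusted p = 0.442 with an estimated correlation). MX1 rose (0.84 ± 0.20). The p53 and apoptosis list gave 13 higher and 3 lower of 31 (13 and 3 adjusted over the list alone, camera adjusted p = 0.0895).

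In the glycolysis and hypoxia list 1 rose and 25 fell of 30 (2 and 26 adjusted over the list alone). Members had a median of -0.68 (camera adjusted p = 2.75e-08, adjusted p = 0.318 with an estimated correlation). LDHA, the lactate dehydrogenase gene, stood at 423 ± 122 against 1738 ± 521 RPKM (-2.02 ± 0.16, adjusted p = 2.39e-08). NDRG1 (-2.5 ± 0.22) and EGLN3 (-2.45 ± 0.25) fell too. In cholesterol synthesis 0 rose and 15 fell of 19 (0 and 16 adjusted over the list alone). Their median was -1.08 (camera adjusted p = 1.45e-07, adjusted p = 0.318 with an estimated correlation). Falls included FDFT1 (-1.65 ± 0.16), the squalene synthase gene, and INSIG1 (-1.63 ± 0.19). Ribosomal protein genes fell together, as 0 rose and 56 fell of 58 (0 and 56 adjusted over the list alone). The set had median -0.62 (camera adjusted p = 9.28e-14, adjusted p = 0.442 with an estimated correlation). RPL4 (-0.91 ± 0.11) and RPS25 (-0.82 ± 0.13) were among them, and some genes of this family have near-identical copies. Of mitochondrially encoded genes 0 rose and 5 fell of 5 (0 and 5 adjusted over the list alone). The median was -1.04 (camera adjusted p = 0.000582, adjusted p = 0.232 with an estimated correlation). Nuclear genes of oxidative phosphorylation gave 5 higher and 15 lower of 56 (3 and 11 adjusted over the list alone, camera adjusted p = 0.131). In the stress response list 2 rose and 13 fell of 25 (3 and 15 adjusted over the list alone). Their median was -0.35 (camera adjusted p = 0.00859, adjusted p = 0.568 with an estimated correlation). The asparagine synthetase gene ASNS fell (-1.21 ± 0.12) and ATF3 rose (0.79 ± 0.10).

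Neuron markers fell early, as 0 rose and 8 fell of 12 (0 and 8 adjusted over the list alone). Across the list the median was -0.76 (camera adjusted p = 1.55e-05, adjusted p = 0.0344 with an estimated correlation). Mesenchyme markers fell, as 1 rose and 14 fell of 23 (1 and 16 adjusted over the list alone). The median was -0.74 (camera adjusted p = 0.000909, adjusted p = 0.442 with an estimated correlation). Among matrix remodelling genes 4 rose and 19 fell of 31 (4 and 19 adjusted over the list alone). The median was -0.61 (camera adjusted p = 0.00181, adjusted p = 0.318 with an estimated correlation). The urokinase gene PLAU rose (1.71 ± 0.13) and SPP1 fell (-2.47 ± 0.27). In the ion transport list 2 rose and 10 fell of 15 (3 and 11 adjusted over the list alone). The median over members was -0.48 (camera adjusted p = 0.0123, adjusted p = 0.386 with an estimated correlation). Leukocyte markers gave 1 higher and 7 lower of 24 (1 and 7 adjusted over the list alone, camera adjusted p = 0.0675), with CD74 at -1.42 ± 0.19. Inflammation genes gave 6 higher and 10 lower of 27 (6 and 10 adjusted over the list alone, camera adjusted p = 0.203). The NF-kB feedback gene TNFAIP3 rose (1.23 ± 0.13) and CXCL14 fell (-3.39 ± 0.23). Heat shock genes gave 10 higher and 5 lower of 20 (10 and 5 adjusted over the list alone, camera adjusted p = 0.230). JAK/STAT genes gave 5 higher and 2 lower of 18 (5 and 2 adjusted over the list alone, camera adjusted p = 0.935). BMP and TGF-beta genes gave 7 higher and 16 lower of 34 (7 and 17 adjusted over the list alone, camera adjusted p = 0.0895).

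Altogether 6226 genes passed at 0 to 48 h, 3366 higher and 2860 lower, and after rescaling 3082 and 3314. Of these, 193 were higher and 694 lower by at least 2-fold. With narrower windows of 0 and 24 h, ATOH1 went from 1.12 ± 0.20 (adjusted p = 0.000180) to 0.36 (adjusted p = 0.253), and the supporting cell list lost its call (adjusted p = 0.0534), as the DNA replication list did without 24 h (adjusted p = 0.182, chosen after seeing the data). PCNA, the replication clamp gene, at 0.37 ± 0.12 (adjusted p = 0.0188), lost its call with narrower windows, without 24 h (0.20, adjusted p = 0.318) and without treated 24 h replicate 2 (0.31, adjusted p = 0.0599).

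Single times placed these changes in order. MYO7A was lower in treated samples at each of the 8 times. It went from -3.92 ± 0.21 at 0 h (limma adjusted p = 4.94e-10) to -1.29 ± 0.21 at 168 h (adjusted p = 0.00445). OTOF was lower at each time too, from -5.1 ± 0.37 at 0 h to -1.76 ± 0.37 at 168 h. ATOH1 stood at 0.45 ± 0.34 at 0 h (adjusted p = 0.371) and 0.27 ± 0.34 at 24 h (adjusted p = 0.574). The difference was 2.63 ± 0.34 at 48 h (adjusted p = 3.02e-05). Libraries at 0 h held 4.0 and 4.8 RPKM (treated) and 2.2 and 3.9 RPKM (control). From 24 to 48 h means went from 14.1 to 16.8 (treated) and 10.8 to 1.87 (control). Differences were 2.55 ± 0.42 at 72 h, 2.71 ± 0.49 at 96 h and 1.82 ± 0.42 at 120 h (adjusted p = 0.0279). At 144 and 168 h ATOH1 stood at 0.97 ± 0.34 (adjusted p = 0.107) and -0.34 ± 0.34 (adjusted p = 0.714). SOX2 was higher from 0 to 96 h, most at 48 h (1.98 ± 0.20). From 0 to 48 h its mean fell from 86.9 to 59.0 RPKM in treated samples and from 46.5 to 14.3 RPKM in controls. LFNG was higher at 24 h (1.19 ± 0.23) and 48 h (1.72 ± 0.23). POU4F3 was lower at 0, 24, 48, 72 and 120 h, from -3.9 ± 0.23 at 0 h to -1.37 ± 0.28 at 120 h. It did not pass at 96, 144 and 168 h. PCNA was higher at 24 h (0.71 ± 0.21) and 48 h (0.67 ± 0.21).

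Several of these calls at single times ended when 1 library was left out. OTOF lost its call at 144 h without control replicate 2 (adjusted p = 0.0723) or treated replicate 1 (adjusted p = 0.0726). At 168 h it lost it without control replicate 1 (-1.38, adjusted p = 0.176) or either treated replicate (adjusted p = 0.0959 and 0.0793). At 120 h the call of ATOH1 ended without treated replicate 1 (1.44, adjusted p = 0.186) and that of POU4F3 without treated replicate 2 (adjusted p = 0.0662). PCNA lost its call at 24 h without control replicate 1 (adjusted p = 0.0802) or treated replicate 2 (adjusted p = 0.137). At 48 h it lost it without any 1 of the 4 libraries of that time (adjusted p from 0.0881 to 0.130). SOX2 at 0 h lost its call without treated replicate 2 (adjusted p = 0.0509). At 96 h each arm had 1 sample, so every p-value for that time rests on the spread within other groups.

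**Figure D2:**
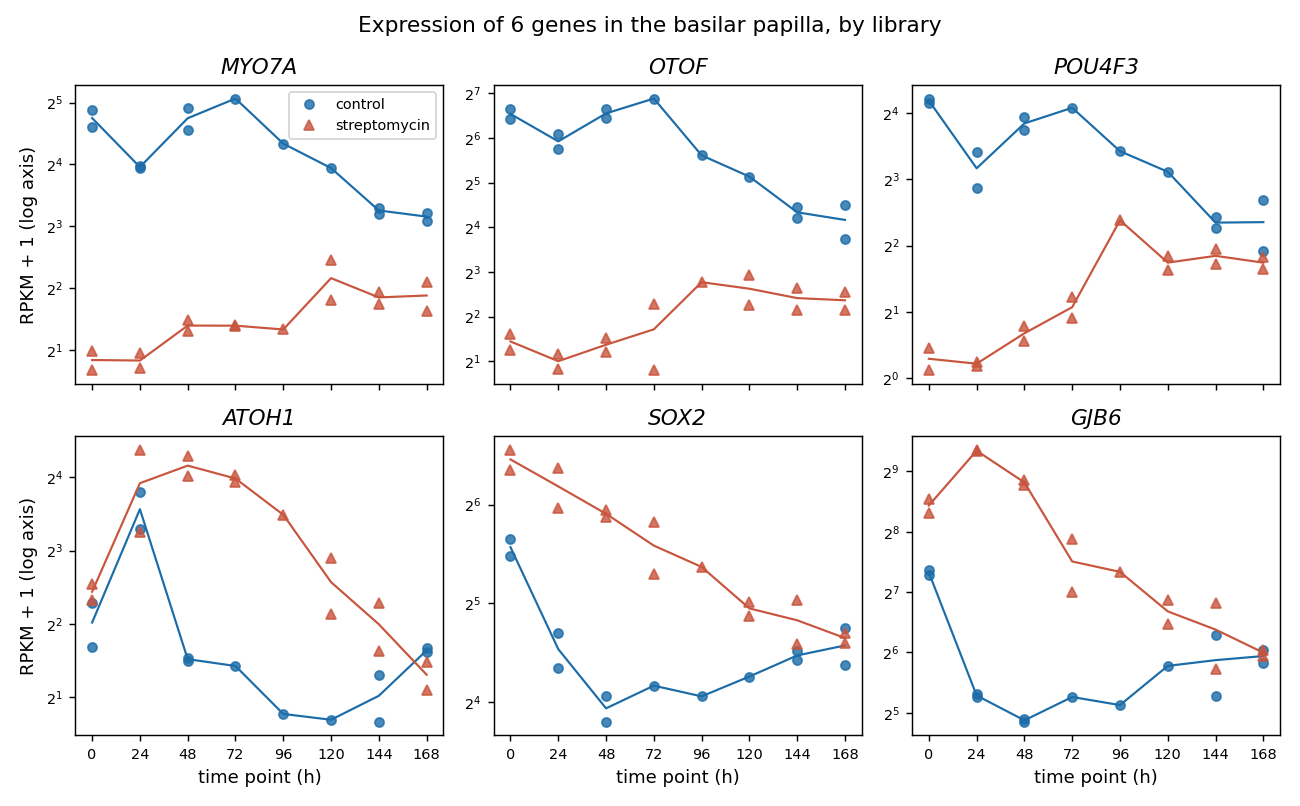
RPKM + 1 on a log axis (vertical) against time in hours (horizontal) for MYO7A, OTOF, POU4F3, ATOH1, SOX2 and GJB6, with points for libraries and lines through the mean at each time, for treated and control samples. ATOH1 at 48 h averaged 16.8 RPKM in treated and 1.87 RPKM in control samples.

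Of the lists, hair cell function genes fell at each time, by counts of 36, 36, 35, 32, 24, 21, 23 and 18 of 42 from 0 to 168 h. Adjusted over the list alone these were 38, 37, 35, 35, 27, 28, 28 and 35. Medians went from -2.36 at 0 h to -0.98 at 168 h, and the test held with an estimated correlation at every time. Supporting cell genes gave 5 higher and 2 lower of 16 (5 and 2 adjusted over the list alone, camera adjusted p = 0.821) at 0 h. In this list 8 rose and 3 fell of 16 (8 and 3 adjusted over the list alone) at 24 h. Their median was 0.75 (camera adjusted p = 0.00431, adjusted p = 0.309 with an estimated correlation). At 48 h 11 rose and 2 fell of 16 (12 and 2 adjusted over the list alone). The median was 1.16 (camera adjusted p = 5.36e-05, adjusted p = 0.0961 with an estimated correlation). At 72 h 7 rose and 2 fell of 16 (8 and 3 adjusted over the list alone). The median was 0.85 (camera adjusted p = 0.0138, adjusted p = 0.293 with an estimated correlation). At 96 h, with 1 sample per arm, 7 rose and 1 fell of 16 (10 and 2 adjusted over the list alone). The median was 1.23 (camera adjusted p = 9.08e-06, adjusted p = 0.0711 with an estimated correlation). At 120 h 1 rose and 0 fell of 16 (1 and 0 adjusted over the list alone). Their median was 0.23 (camera adjusted p = 0.00661, adjusted p = 0.365 with an estimated correlation). DNA replication genes gave 2 higher and 2 lower of 28 (2 and 2 adjusted over the list alone, camera adjusted p = 0.215) at 0 h. They rose at 24 h, as 17 rose and 0 fell of 28 (19 and 0 adjusted over the list alone). The list median was 0.62 (camera adjusted p = 1.72e-05, adjusted p = 0.309 with an estimated correlation). At 48 h 11 rose and 0 fell of 28 (12 and 0 adjusted over the list alone). The median was 0.41 (camera adjusted p = 0.000236, adjusted p = 0.493 with an estimated correlation). At 72 h they gave 0 higher and 0 lower of 28 (0 and 0 adjusted over the list alone, camera adjusted p = 0.117), with 3 members at an unadjusted p under 0.05.

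Mitosis genes gave 0 higher and 1 lower of 31 (0 and 0 adjusted over the list alone, camera adjusted p = 0.204) in the direct test of late minus early effects, and calls of both signs at single times. At 0 h limma called few members, as 0 rose and 2 fell of 31 (0 and 0 adjusted over the list alone), and 4 had an unadjusted p under 0.05. The median was -0.35 (camera adjusted p = 0.00456, adjusted p = 0.798 with an estimated correlation). The call at 0 h ended without treated replicate 2 (adjusted p = 0.111). At 48 h they were higher, as 6 rose and 0 fell of 31 (5 and 0 adjusted over the list alone). Members had a median of 0.44 (camera adjusted p = 0.00113, adjusted p = 0.509 with an estimated correlation). At 72 h limma called no member, as 0 rose and 0 fell of 31 (0 and 0 adjusted over the list alone), with 0 at an unadjusted p under 0.05. Their median was -0.26 (camera adjusted p = 0.0138, adjusted p = 0.680 with an estimated correlation). Without treated replicate 2 that call ended and the median turned to 0.016. At 144 h they were lower, as 0 rose and 1 fell of 31 (0 and 1 adjusted over the list alone). The set had median -0.36 (camera adjusted p = 0.000303, adjusted p = 0.604 with an estimated correlation).

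Glycolysis and hypoxia genes fell at 24 h, as 1 rose and 22 fell of 30 (1 and 22 adjusted over the list alone). The median was -0.80 (camera adjusted p = 3.74e-08, adjusted p = 0.309 with an estimated correlation). At 72 h they went the other way, as 3 rose and 0 fell of 30 (3 and 0 adjusted over the list alone). Their median was 0.30 (camera adjusted p = 0.0417, adjusted p = 0.680 with an estimated correlation). That call ended with rescaling (adjusted p = 0.0601) and without treated replicate 1 (adjusted p = 0.979).

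The largest single changes shifted with time. They were USP40 1.91, AQP5 1.85, FAM70B -5.3 and SNCG -5.29 at 0 h. At 24 h they were AQP5 5.38, GJB6 4.06, FAM70B -5.76 and OCM2 -5.73. At 48 h they were NOXO1 4.3, GJB6 3.94, OCM2 -6.9 and FAM70B -5.78. At 72 h they were NOXO1 3.64, AVP 3.64, OCM2 -7.32 and FAM70B -5.81, where AVP is the gene of the vasotocin hormone precursor. At 96 h, with 1 sample per arm, TECTA (4.48) and AVP (3.79) rose and OCM2 (-6.79) and SNCG fell. SNCG was listed at 0 in the treated sample. The changes were CCK 2.9, HSP25 2.18, OCM2 -5.56 and FAM70B -4.46 at 120 h and CCK 2.57, TECTA 2.32, OCM2 -4.44 and FAM70B -3.41 at 144 h. At 168 h they were MYO15B 1.36, FGF19 1.27, OCM2 -4.5 and FAM70B -3.29. The calls of all 6 rises named at 120, 144 and 168 h ended when some 1 library was left out. Examples are TECTA at 144 h without treated replicate 2 (1.35, adjusted p = 0.274) or control replicate 1 (1.75, adjusted p = 0.204), and CCK at 120 h without treated replicate 1 (adjusted p = 0.152). AQP5 at 0 h lost its call without treated replicate 2 (1.46, adjusted p = 0.161).

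The number of genes past the test was 3109 at 0 h (1778 higher, 1331 lower) and 4476 at 24 h (2243 higher, 2233 lower). It was 3369 at 48 h (1678 higher, 1691 lower) and 1677 at 72 h (762 higher, 915 lower). At 96 h it was 479 (226 higher, 253 lower) and at 120 h 311 (33 higher, 278 lower). At 144 h it was 717 (193 higher, 524 lower) and at 168 h 141 (15 higher, 126 lower). After median-of-ratios rescaling the split was 1624 and 1700 at 0 h, 74 and 191 at 120 h, 369 and 594 at 144 h and 38 and 103 at 168 h, and the median of all genes at 120 h moved from -0.135 to -0.01. Counts at single times moved by over 1.5 times when some libraries were left out, for example to 128 at 144 h without control replicate 2.

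**Figure D3:**
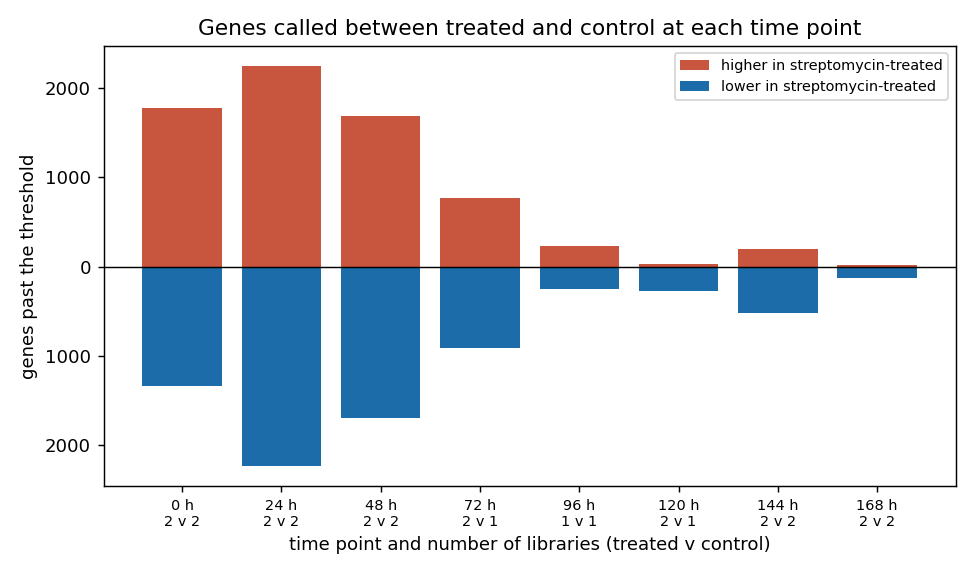
Number of genes with adjusted p under 0.05 (vertical axis) that were higher or lower in treated samples at each time in hours (horizontal axis). The count was 4476 at 24 h and 141 at 168 h.

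At 120 to 168 h, the last 3 times, hair cell genes were still lower in treated papillae (n = 6 treated and 5 control). OCM2 stood at 3.66 ± 1.6 against 121 ± 52.6 RPKM (-4.83 ± 0.23, limma adjusted p = 2.08e-10). OTOF stood at 4.55 ± 1.23 against 21.3 ± 8.11 RPKM (-2.08 ± 0.23, adjusted p = 8.01e-06) and MYO7A at 2.91 ± 0.853 against 9.45 ± 2.79 (-1.51 ± 0.13, adjusted p = 8.17e-07). Other large falls were FAM70B -3.72 ± 0.12, TMC2 -3.13 ± 0.11, SNCG -3.01 ± 0.18, NELL1 -2.94 ± 0.12, TMPRSS3 -2.91 ± 0.13, SS2 -2.91 ± 0.25 and SLC17A8 -2.7 ± 0.13. Furthest above control was CCK, the cholecystokinin gene, at 39.5 ± 13.8 against 6.21 ± 3.39 RPKM (2.55 ± 0.34, adjusted p = 6.32e-05). The heat shock gene HSP25 stood at 302 ± 74.8 against 86.2 ± 17.7 RPKM (1.82 ± 0.25). ATP6V0D2, a proton pump gene, differed by 1.59 ± 0.19. Others were MSMB 1.84 ± 0.31, ABI3BP 1.46 ± 0.15, USP40 1.36 ± 0.23, MGP 1.43 ± 0.45 and TECTA 1.41 ± 0.38. Each was higher in 6 of 6 treated libraries except TECTA (5 of 6). CCK, ATP6V0D2 and TECTA fell over time in controls.

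Of the hair cell function list late, 0 rose and 35 fell of 42 (1 and 37 adjusted over the list alone). Across the list the median was -1.02 (camera adjusted p = 9.76e-26, adjusted p = 0.00923 with an estimated correlation). Early hair cell genes gave 1 higher and 4 lower of 8 (1 and 4 adjusted over the list alone, camera adjusted p = 0.110). Falls included GFI1 -1.75 ± 0.14, LHX3 -1.35 ± 0.20 and POU4F3 -0.81 ± 0.14. Supporting cell genes gave 3 higher and 2 lower of 16 (3 and 3 adjusted over the list alone, camera adjusted p = 0.144). PROX1, a transcription factor gene of supporting cells, rose (0.91 ± 0.11). Leukocyte markers fell, as 0 rose and 15 fell of 24 (1 and 21 adjusted over the list alone). The median was -0.63 (camera adjusted p = 3.54e-06, adjusted p = 0.451 with an estimated correlation). CD74 stood at 36.1 ± 10.9 against 94.9 ± 24.2 RPKM (-1.32 ± 0.20), and RAC2 fell (-1.1 ± 0.19). Of neuron markers 0 rose and 6 fell of 12 (1 and 6 adjusted over the list alone). The median was -0.47 (camera adjusted p = 0.00163, adjusted p = 0.172 with an estimated correlation). Of glia markers 0 rose and 6 fell of 12 (0 and 6 adjusted over the list alone). The median over members was -0.32 (camera adjusted p = 0.0297, adjusted p = 0.451 with an estimated correlation). NGFR, the p75 neurotrophin receptor gene, fell (-1.9 ± 0.25), as did the myelin gene PMP2 (-1.18 ± 0.25).

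BMP and TGF-beta genes fell late, as 0 rose and 11 fell of 34 (0 and 16 adjusted over the list alone). Their median was -0.24 (camera adjusted p = 0.00606, adjusted p = 0.451 with an estimated correlation). Mitochondrially encoded genes fell, as 0 rose and 4 fell of 5 (0 and 5 adjusted over the list alone). The median was -0.56 (camera adjusted p = 0.00606, adjusted p = 0.451 with an estimated correlation). Heat shock genes rose, as 7 rose and 1 fell of 20 (8 and 1 adjusted over the list alone). The median was 0.10 (camera adjusted p = 0.00163, adjusted p = 0.633 with an estimated correlation). HSPB8 (0.84 ± 0.19) and HSPH1 (0.52 ± 0.10) were among them. Ribosomal protein genes were higher as a set although limma called no member alone, as 0 rose and 0 fell of 58 (0 and 0 adjusted over the list alone), and 2 had an unadjusted p under 0.05. The median was 0.14 (camera adjusted p = 1.56e-05, adjusted p = 0.772 with an estimated correlation). In the stress response list 3 rose and 1 fell of 25 (3 and 1 adjusted over the list alone). Their median was 0.04 (camera adjusted p = 0.0297, adjusted p = 0.772 with an estimated correlation). In the mitosis list 0 rose and 3 fell of 31 (0 and 1 adjusted over the list alone). The list median was -0.28 (camera adjusted p = 0.0228, adjusted p = 0.772 with an estimated correlation). Mesenchyme markers gave 0 higher and 4 lower of 23 (0 and 0 adjusted over the list alone, camera adjusted p = 0.967). Cholesterol synthesis genes gave 0 higher and 0 lower of 19 (0 and 0 adjusted over the list alone, camera adjusted p = 0.795), with 0 members at an unadjusted p under 0.05. Glycolysis and hypoxia genes gave 2 higher and 2 lower of 30 (2 and 1 adjusted over the list alone, camera adjusted p = 0.0967). Wnt genes gave 3 higher and 7 lower of 32 (3 and 8 adjusted over the list alone, camera adjusted p = 0.967). SFRP1 (-1.26 ± 0.14) and WNT4 (-1.19 ± 0.19) fell, while WNT7A (0.64 ± 0.16) and FZD7 (0.43 ± 0.11) rose. Cartilage markers gave 1 higher and 3 lower of 13 (2 and 3 adjusted over the list alone, camera adjusted p = 0.475). COL9A3 (-1.82 ± 0.24) and CHAD (-1.69 ± 0.18) fell, while COL2A1 rose (0.83 ± 0.18).

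In total 2369 genes passed at 120 to 168 h, 525 higher and 1844 lower, and after rescaling the split was 1154 and 1442. By at least 2-fold, 32 were higher and 201 lower. Calls ended for ATOH1 (0.82 ± 0.21, adjusted p = 0.0133) with narrower windows (0.31, adjusted p = 0.424), SOX2 (0.37 ± 0.13, adjusted p = 0.0474) under 21 alternatives, TECTA (adjusted p = 0.0158) without treated 168 h replicate 1 (1.2, adjusted p = 0.0502) and MGP (adjusted p = 0.0334) with no filter (adjusted p = 0.0692), each also under others. List calls ended for glia with pseudocount 0.1 (adjusted p = 0.0664) and without control 144 h replicate 2 (median -0.273). They ended for the stress response without treated 120 h replicate 2 (median -0.097), control 168 h replicate 1 (0.015) or 24 and 168 h (adjusted p = 0.138). Those of mitosis ended without control 168 h replicate 2 (median -0.201), treated 120 h replicate 2 (-0.273) or treated 168 h replicate 1 (-0.22).

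The difference between the late and early effects was tested directly, as the effect at 120 to 168 h minus that at 0 to 48 h (n = 12 treated and 11 control). Hair cell genes lay closer to control late than early. The late effect exceeded the early one by 2.99 ± 0.31 for OTOF (limma adjusted p = 4.14e-06), 2.51 ± 0.20 for POU4F3 (adjusted p = 2.98e-07) and 1.96 ± 0.18 for MYO7A (adjusted p = 1.36e-06). Some genes of supporting cells and of Notch signalling went the other way, although neither list passed. GJB6 stood at -2.55 ± 0.27 (adjusted p = 5.79e-06), SOX2 at -1.13 ± 0.17 (adjusted p = 0.000135), NOTCH1 at -1.74 ± 0.14 and LFNG at -1.22 ± 0.20. The largest positive differences were those of SCG3, a secretory granule gene (3.43 ± 0.18), and U3 3.36 ± 0.63, VIP 3.21 ± 0.31, NDRG1 3.17 ± 0.32, CHGA 3.12 ± 0.53, SKA3 3.01 ± 0.34 and KCNAB1 2.87 ± 0.19. The largest negative differences were those of AQP5 (-2.87 ± 0.46) and TRPM3 -2.2 ± 0.25, ABHD6 -2.18 ± 0.28, PLEKHG1 -2.07 ± 0.24, NOXO1 -2.01 ± 0.48, BTG2 -1.97 ± 0.28 and COL9A3 -1.87 ± 0.32.

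For the difference, in the hair cell function list 32 were higher and 2 lower of 42 (33 and 3 adjusted over the list alone). The median was 1.2 (camera adjusted p = 1.12e-21, adjusted p = 0.0193 with an estimated correlation). In the early hair cell list 4 were higher and 0 lower of 8 (4 and 0 adjusted over the list alone). The median was 0.72 (camera adjusted p = 0.00102, adjusted p = 0.373 with an estimated correlation). LHX3 (1.99 ± 0.27) and GFI1 (1.64 ± 0.19) were higher. Supporting cell genes gave 1 higher and 8 lower of 16 (1 and 9 adjusted over the list alone, camera adjusted p = 0.0552). Notch genes gave 3 higher and 6 lower of 15 (3 and 6 adjusted over the list alone, camera adjusted p = 0.287). EYA1 (-1.69 ± 0.15) and GATA3 (-1.54 ± 0.22) were lower. Of ribosomal protein genes 53 were higher and 0 lower of 58 (57 and 0 adjusted over the list alone). Members had a median of 0.74 (camera adjusted p = 1.12e-21, adjusted p = 0.394 with an estimated correlation). In glycolysis and hypoxia 19 were higher and 1 lower of 30 (21 and 1 adjusted over the list alone). Their median was 0.79 (camera adjusted p = 8.32e-11, adjusted p = 0.373 with an estimated correlation). In cholesterol synthesis 14 were higher and 0 lower of 19 (15 and 0 adjusted over the list alone). The set had median 1.03 (camera adjusted p = 7.73e-09, adjusted p = 0.373 with an estimated correlation). In the stress response list 9 were higher and 1 lower of 25 (10 and 1 adjusted over the list alone). The median was 0.43 (camera adjusted p = 9.34e-05, adjusted p = 0.394 with an estimated correlation).

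Of neuron markers 6 were higher and 1 lower of 12 (6 and 1 adjusted over the list alone). Their median was 0.61 (camera adjusted p = 0.000875, adjusted p = 0.162 with an estimated correlation). Of mesenchyme markers 6 were higher and 1 lower of 23 (6 and 1 adjusted over the list alone). Across the list the median was 0.55 (camera adjusted p = 0.00141, adjusted p = 0.522 with an estimated correlation). Of DNA replication genes 0 were higher and 17 lower of 28 (0 and 20 adjusted over the list alone). The median was -0.53 (camera adjusted p = 0.000457, adjusted p = 0.394 with an estimated correlation). Of immediate early genes 0 were higher and 10 lower of 15 (0 and 10 adjusted over the list alone). The median was -0.89 (camera adjusted p = 0.000548, adjusted p = 0.394 with an estimated correlation). Of interferon genes 0 were higher and 10 lower of 21 (0 and 10 adjusted over the list alone). The median over members was -0.49 (camera adjusted p = 0.00131, adjusted p = 0.394 with an estimated correlation). Of mitochondrially encoded genes 3 were higher and 0 lower of 5 (4 and 0 adjusted over the list alone). Their median was 0.52 (camera adjusted p = 0.0243, adjusted p = 0.394 with an estimated correlation). Of nuclear genes of oxidative phosphorylation 7 were higher and 3 lower of 56 (4 and 3 adjusted over the list alone). The median was 0.16 (camera adjusted p = 0.0243, adjusted p = 0.762 with an estimated correlation). Of matrix remodelling genes 5 were higher and 3 lower of 31 (3 and 0 adjusted over the list alone). The median was 0.34 (camera adjusted p = 0.0293, adjusted p = 0.394 with an estimated correlation).

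The test of the difference passed for 4205 genes, 1539 higher and 2666 lower. Of these, 484 were higher and 276 lower by at least 2-fold. Rescaling moved the median of all genes from -0.122 to -0.003 and the split to 2219 and 1929. The matrix list lost its call with rescaling (adjusted p = 0.0712), without 24 and 168 h (adjusted p = 0.131, chosen after seeing the data) and without any 1 of 5 libraries (adjusted p from 0.0504 to 0.0869). Calls also ended for the nuclear oxidative phosphorylation list without any 1 of 6 libraries (medians -0.002 to 0.108), the mitochondrially encoded list without 24 and 168 h (adjusted p = 0.0644), and NOXO1 with narrower windows (-0.89, adjusted p = 0.262) and without 24 and 168 h (adjusted p = 0.0517).

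Controls alone were compared between late and early times to show what changed without the drug (120 to 168 h minus 0 to 48 h, n = 5 and 6). The tectorial membrane gene TECTB stood at 43 ± 23.3 against 1276 ± 302 RPKM (-4.95 ± 0.32, limma adjusted p = 4.83e-09). CCK stood at 6.21 ± 3.39 against 209 ± 118 RPKM (-4.79 ± 0.34). GSN, the gene of the actin-severing protein gelsolin, stood at 264 ± 59.6 against 4237 ± 1072 RPKM (-4.05 ± 0.30). The serine synthesis gene PHGDH rose to 218 ± 34.7 against 12.7 ± 12.9 RPKM (4.76 ± 0.26, adjusted p = 1.56e-09). FOXD3, a transcription factor gene of the neural crest, rose by 4.04 ± 0.23 and NGFR by 3.86 ± 0.25. Other large rises were FABP5 3.9 ± 0.28, LGALS1 3.76 ± 0.25, BPI 3.64 ± 0.22, SPON2 3.36 ± 0.17 and ACTA2 3.33 ± 0.16. Other large falls were ATP12A -3.19 ± 0.16, ATP6V0D2 -3.04 ± 0.19, TECTA -3.02 ± 0.38, C-16 -2.98 ± 0.30 and OTOA -2.87 ± 0.24. The 8 largest rises and 8 largest falls were each seen in 5 of 5 late control libraries against the mean of the early ones.

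Hair cell genes fell in controls too, as 1 rose and 35 fell of 42 (1 and 35 adjusted over the list alone). The median was -1.11 (camera adjusted p = 2.15e-18, adjusted p = 0.0357 with an estimated correlation). Examples were KCNAB1 -2.52 ± 0.14, FSCN2 -2.24 ± 0.15, OTOF -1.81 ± 0.23 and MYO7A -1.03 ± 0.13, while PVALB rose (1.75 ± 0.20). Early hair cell genes fell, as 0 rose and 6 fell of 8 (0 and 6 adjusted over the list alone). Their median was -0.97 (camera adjusted p = 0.000365, adjusted p = 0.216 with an estimated correlation). LHX3 (-1.29 ± 0.20), ATOH1 (-1.24 ± 0.21) and POU4F3 (-1.13 ± 0.14) were among them. Supporting cell genes fell, as 1 rose and 9 fell of 16 (1 and 9 adjusted over the list alone). The list median was -0.61 (camera adjusted p = 0.000533, adjusted p = 0.171 with an estimated correlation). LFNG rose (1.41 ± 0.15). Neuron markers fell, as 3 rose and 7 fell of 12 (3 and 8 adjusted over the list alone). The median was -0.71 (camera adjusted p = 0.00266, adjusted p = 0.171 with an estimated correlation). Glycolysis and hypoxia genes fell, as 3 rose and 16 fell of 30 (3 and 17 adjusted over the list alone). The median was -0.43 (camera adjusted p = 0.000489, adjusted p = 0.479 with an estimated correlation).

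Leukocyte markers rose in controls, as 20 rose and 2 fell of 24 (20 and 2 adjusted over the list alone). Members had a median of 1.83 (camera adjusted p = 3.29e-08, adjusted p = 0.242 with an estimated correlation). LY86 reached 27 ± 6.33 against 2.64 ± 2.65 RPKM (3.18 ± 0.23) and the cathepsin gene CTSS 104 ± 14.3 against 18.5 ± 13.1 (2.67 ± 0.19). Mesenchyme markers rose, as 17 rose and 1 fell of 23 (17 and 1 adjusted over the list alone). Their median was 1.05 (camera adjusted p = 0.000243, adjusted p = 0.476 with an estimated correlation). Melanocyte markers rose, as 8 rose and 0 fell of 8 (8 and 0 adjusted over the list alone). The set had median 1.14 (camera adjusted p = 6.94e-05, adjusted p = 0.0671 with an estimated correlation). They included GPNMB (2.3 ± 0.21), which macrophages also express. Inflammation genes rose, as 17 rose and 1 fell of 27 (17 and 1 adjusted over the list alone). The median was 0.75 (camera adjusted p = 0.000702, adjusted p = 0.317 with an estimated correlation).

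Of JAK/STAT genes 12 rose and 0 fell of 18 (12 and 0 adjusted over the list alone) in controls. Their median was 0.47 (camera adjusted p = 0.00370, adjusted p = 0.216 with an estimated correlation). Of interferon genes 12 rose and 0 fell of 21 (12 and 0 adjusted over the list alone). Across the list the median was 0.63 (camera adjusted p = 0.00321, adjusted p = 0.479 with an estimated correlation). Of matrix remodelling genes 18 rose and 3 fell of 31 (18 and 3 adjusted over the list alone). The median was 0.57 (camera adjusted p = 0.00433, adjusted p = 0.317 with an estimated correlation). In the stress response list 21 rose and 1 fell of 25 (23 and 1 adjusted over the list alone). The median was 0.82 (camera adjusted p = 1.42e-06, adjusted p = 0.320 with an estimated correlation). Of mitochondrially encoded genes 5 rose and 0 fell of 5 (5 and 0 adjusted over the list alone). The median over members was 1.02 (camera adjusted p = 0.00105, adjusted p = 0.203 with an estimated correlation). Of ribosomal protein genes 44 rose and 0 fell of 58 (47 and 0 adjusted over the list alone). Their median was 0.50 (camera adjusted p = 7.00e-07, adjusted p = 0.625 with an estimated correlation). In the p53 and apoptosis list 12 rose and 4 fell of 31 (12 and 4 adjusted over the list alone). The median was 0.22 (camera adjusted p = 0.0387, adjusted p = 0.574 with an estimated correlation). In all 5971 genes passed in controls, 3498 higher and 2473 lower, and after rescaling 3013 and 3219. The p53 list lost its call with narrower windows (adjusted p = 0.0665) and without control 168 h replicate 2 (adjusted p = 0.0564).

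**Figure D4:**
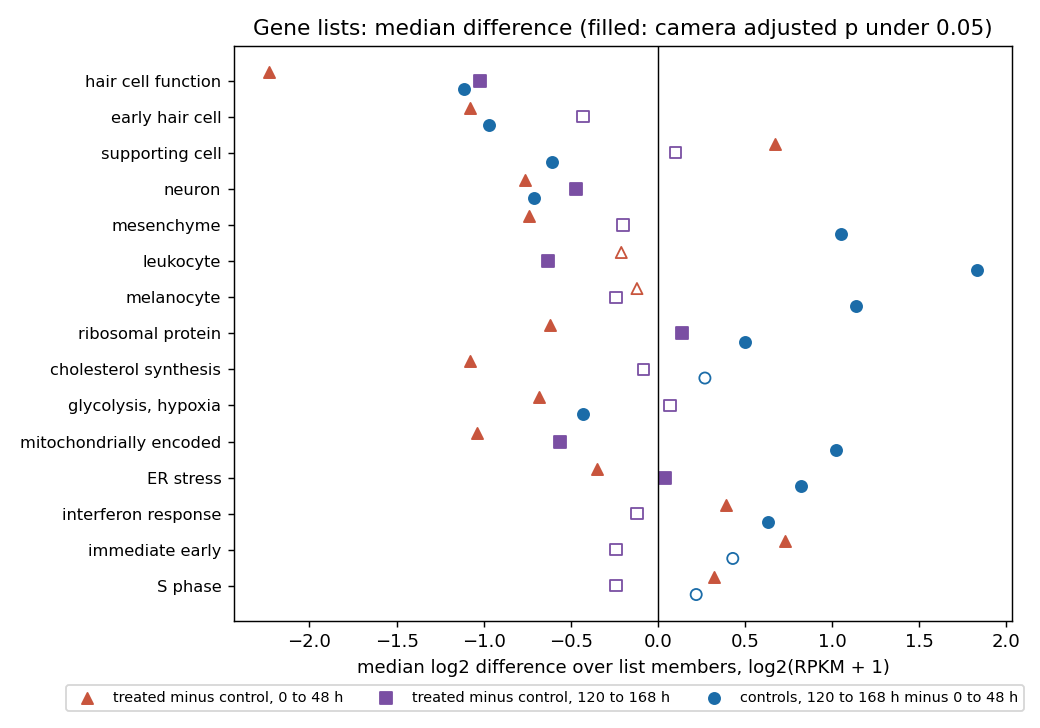
Median log2 difference over the members of each gene list (horizontal axis) for treated minus control at 0 to 48 h, treated minus control at 120 to 168 h, and controls late minus early, with filled symbols where the camera adjusted p was under 0.05. The hair cell function list had medians of -2.23, -1.02 and -1.11.

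Of the 12 genes chosen beforehand, SOX21 and HES5 were not among the tested features. The calcium-binding protein gene CALB2 stood at -0.51 ± 0.21 over all times (limma adjusted p = 0.0512). With a replicate block it was -0.54 (adjusted p = 0.0353). Early it stood at -0.10 ± 0.25 (adjusted p = 0.758) and late at -1.02 ± 0.27 (adjusted p = 0.0142). The late call ended without 168 h (-0.86, adjusted p = 0.117). For the difference CALB2 stood at -0.91 ± 0.37 (adjusted p = 0.0641, and 0.0201 with the replicate block) and in controls at -0.12 ± 0.27 (adjusted p = 0.732). CDK1, the mitotic kinase gene, did not pass. It stood at -0.27 ± 0.13 over all times (adjusted p = 0.104), -0.30 ± 0.19 early, -0.36 ± 0.21 late, -0.06 ± 0.28 for the difference and 0.22 ± 0.21 in controls. PCNA stood at 0.17 ± 0.10 over all times (adjusted p = 0.194) and -0.07 ± 0.13 late (adjusted p = 0.750). For the difference PCNA stood at -0.44 ± 0.18 (adjusted p = 0.0686, and 0.0220 with the replicate block) and in controls at 0.17 ± 0.13 (adjusted p = 0.302).

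TECTA stood at 0.62 ± 0.35 early (adjusted p = 0.156) and 0.79 ± 0.52 for the difference (adjusted p = 0.254). Early it was higher in 4 of 6 libraries, passed with only the samples compared (adjusted p = 0.0135) and turned to -0.479 with narrower windows. ATOH1 had a difference of effects of -0.30 ± 0.29 (adjusted p = 0.458). LFNG stood at -0.09 ± 0.15 late (adjusted p = 0.709) and SOX2 at -0.24 ± 0.13 in controls (adjusted p = 0.121, and -0.34 with adjusted p = 0.0109 after rescaling).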

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

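The tests chosen only after the result was seen are the change of hair cell genes within treated and within control samples, the spread and the rescaled count late against early, the comparison of supporting cell genes with other cell types, and the comparison of treated samples over time.

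A difference between times called these results for a closer look, by the direct test of the late effect (120 to 168 h) minus the early effect (0 to 48 h), which 4205 genes passed. Of 100 splits 1 gave as many (the real one), and the highest other was 2980. It was 1156 among the 9 parting as many pairs of samples of equal time and number. Splits mix the groups, so chance is not excluded. The named genes with higher late effects were SCG3 (3.43), U3 (3.36), VIP (3.21), NDRG1 (3.17), CHGA (3.12), SKA3 (3.01), OTOF (2.99), KCNAB1 (2.87), POU4F3 (2.51) and MYO7A (1.96). Those with lower late effects were AQP5 (-2.87), GJB6 (-2.55), TRPM3 (-2.20), ABHD6 (-2.18), PLEKHG1 (-2.07), NOXO1 (-2.01), BTG2 (-1.97), COL9A3 (-1.87), LFNG (-1.22) and SOX2 (-1.13). Medians of the lists were 1.2 for hair cell function, 0.72 for early hair cells, 1.03 for cholesterol synthesis, 0.79 for glycolysis and hypoxia, 0.74 for ribosomal proteins, 0.61 for neurons, 0.55 for mesenchyme, 0.52 for mitochondrially encoded genes, 0.43 for the stress response, 0.34 for matrix remodelling, 0.16 for nuclear oxidative phosphorylation, -0.49 for interferon, -0.53 for DNA replication and -0.89 for immediate early genes. Of these lists, hair cell function alone held with an estimated correlation (adjusted p = 0.0193).

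Hair cell function genes were closer to control late than early, by a median of 1.2. A rise of these genes in treated samples is argued against as the whole cause, since their median change there was 0.07 (95% bootstrap interval over members -0.01 to 0.12), and compression of low values by the pseudocount is argued against too, since with pseudocount 0.1 that median was 0.19 (-0.03 to 0.42). In controls the same genes fell by a median of -1.11 (-1.44 to -0.92). A decline there may explain most of the list's narrowing, as a hypothesis from the same data. OTOF and MYO7A rose in treated samples, and POU4F3 (off this list) by more than it fell in controls. Whether the decline reflects fewer hair cells or less RNA per hair cell was not tested.

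Fewer genes differed late (2369) than early (6226). Lower precision late is argued against as the whole cause. The noise-corrected SD of log2 differences late was 0.54 of that early (0.315 against 0.584, over 5531 features of mean RPKM 10 or more). A change of scale between libraries is argued against as well, since after rescaling 2596 genes passed late. Recovery of treated tissue, convergence of both arms in culture and precision (noise was pooled over times) stay open.

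Supporting cell genes were higher in treated samples early (median 0.67). Loss of hair cells from the mixed tissue would raise other cell types alike, but the supporting cell median lay 1.02 (0.55 to 1.59) above the pooled median of mesenchyme, endothelium, glia and leukocyte markers (-0.34, 70 members). A change of scale is argued against by the rescaled test (camera adjusted p = 0.0035), although the list was not called with an estimated correlation (adjusted p = 0.318). A larger share of sensory epithelium in the tissue, expression per supporting cell or a fall in controls may contribute, not told apart by the 1.02. At 0 h the list did not pass.

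For each other count 1 of 100 splits was as large (the real one), which likewise cannot exclude chance. The real count and the highest other were 5111 and 1238 over all times, 6226 and 3821 at 0 to 48 h, 2369 and 1192 at 120 to 168 h, 5971 and 1851 in controls over time, and 6665 and 3737 in treated samples over time. Among splits that part as many pairs, the highest others were 0 of 6 splits over all times, 3587 of 28 at 0 to 48 h and 990 of 28 at 120 to 168 h.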

How the results depend on the processing

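The fits without 72, 96 and 120 h, the fits without 24 and 168 h, and the comparison of treated samples over time were chosen only after the results were seen. Values are log2 differences or numbers of genes, and unless stated the cause was not tested.

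Counts stayed within 1.5 times under the alternatives run, except 120 h with pseudocount 0.1 (193), 120 to 168 h with only the samples compared (1550, with fewer samples to estimate the spread), 120 to 168 h without 168 h (1414) and the difference without 24 and 168 h (1959), both with fewer samples, and 168 h with the replicate block (243). The block gave 5246 over all times (4430 within each time), 6688 at 0 to 48 h, 2946 at 120 to 168 h, 4834 for the difference and 6471 in controls, and changed no other count by over 1.5 times. It ended the calls of BTG2, ID2, IL6ST, RSAD2 and SOX10 over all times, and of the early hair cell list at 144 h (adjusted p = 0.0556) and the interferon list at 24 h (adjusted p = 0.0534). CALB2 (all times, difference), PCNA (difference, treated samples over time), LFNG (0 and 96 h) and TECTA (72 h) came to pass with it.

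Leaving out 1 library at a time gave 1553–3304 genes at 0 h, 3243–4606 at 24 h, 1727–3523 at 48 h, 953–1811 at 72 h, 410–514 at 96 h, 145–340 at 120 h, 128–793 at 144 h, 43–207 at 168 h, 4578–5168 over all times, 5534–6335 at 0 to 48 h, 1713–2664 at 120 to 168 h, 3685–4387 for the difference, 5425–6076 in controls and 6050–6735 in treated samples over time. A lone remaining sample is assumed to vary like the other groups. Counts fell by over 1.5 times at 0 h without control 1 or 2 (1659, 1901) or treated 1 or 2 (1895, 1553), at 48 h without control 1 or 2 (2008, 1727) or treated 1 or 2 (1953, 1870), at 72 h without treated 2 (953), at 120 h without treated 1 or 2 (145, 206), at 144 h without control 1 or 2 (358, 128) or treated 1 or 2 (219, 266), and at 168 h without control 1 or 2 (91, 67) or treated 1 (43), each with fewer samples.

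Signs turned for values that did not pass, except THBS2 at 0 to 48 h (0.48, adjusted p = 0.046), which was -0.415 with narrower windows, and the leukocyte list at 168 h, whose test turned without treated 1 while its median ranged from -0.876 to -0.091. Others were TECTA at 0 to 48 h (-0.479) and CALB2 in controls (0.057) with narrower windows, CDK1 for the difference (0.073 rescaled, 0.183 with narrower windows), PCNA at 120 to 168 h rescaled (0.010), LFNG at 120 h with the block (-0.072) and at 120 to 168 h without 168 h (0.009). Leaving out 1 library turned ATOH1 at 24 h (-0.289 to 0.829), CALB2 at 0 to 48 h (-0.349 to 0.144), 24 h (-0.86 to 0.617) and in controls (-0.37 to 0.123), CDK1 at 72 h (-0.611 to 0.27), 120 h (-0.525 to 0.002), 168 h (-0.863 to 0.336) and for the difference (-0.256 to 0.143), LFNG at 120 h (-0.14 to 0.29), 144 h (-0.247 to 0.133), 168 h (-0.664 to 0.075) and 120 to 168 h (-0.215 to 0.031), PCNA at 72 h (-0.073 to 0.463), 120 h (-0.375 to 0.05), 144 h (-0.002 to 0.167), 168 h (-0.454 to 0.177) and 120 to 168 h (-0.178 to 0.032), SOX2 at 168 h (-0.101 to 0.274) and TECTA at 24 h (-0.151 to 1.11) and 168 h (-0.458 to 1.515).

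Of single-gene results, 814 kept direction and call with pseudocount 0.1 (31 no longer passed), 789 with no filter (57), 833 with no trend (13), 810 with rescaling (28), 487 with narrower windows (89) and 415 with only the samples compared (24). Of list calls, 16 held with the estimated correlation and 165 did not, 175 held with rescaling (6 did not), 177 with pseudocount 0.1 (4) and 174 with no filter (7). Summing features that share a symbol was not run, since 0 features share one. Depth of at least 16.48 M alignments leaves genes near 1 RPKM the least precise.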

Other observations

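The comparison of treated samples at 120 to 168 h with those at 0 to 48 h was chosen after seeing the data, and GFI1 and LHX3 were named in it after their values were seen (n = 6 and 6). POU4F3 rose (2.43 ± 0.298 against 0.330 ± 0.242 RPKM, 1.38 ± 0.13, limma adjusted p = 1.96e-07), as did OTOF (4.55 ± 1.23 against 1.44 ± 0.462, 1.18 ± 0.21, adjusted p = 0.000140), MYO7A (2.91 ± 0.853 against 1.06 ± 0.475, 0.93 ± 0.12, adjusted p = 6.15e-06), GFI1 (0.79 ± 0.13) and LHX3 (0.69 ± 0.18), each in 6 of 6 late libraries. ATOH1 fell (3.13 ± 1.93 against 11.8 ± 6.9 RPKM, -1.54 ± 0.20, adjusted p = 4.85e-06), as did SOX2 (27.1 ± 3.97 against 72.6 ± 14.6, -1.37 ± 0.12, adjusted p = 4.82e-08) and TECTA (-2.23 ± 0.35). CALB2 fell (-1.04 ± 0.25), a call lost with narrower windows (-0.44, adjusted p = 0.245). LFNG (0.19 ± 0.13), CDK1 (0.16 ± 0.19) and PCNA (-0.27 ± 0.12) did not pass. The hair cell function list as a set did not pass (7 higher and 8 lower of 42 (6 and 8 adjusted over the list alone, camera adjusted p = 0.701)), and 6665 genes passed in all, 3021 higher and 3644 lower.

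In treated samples 11 lists were higher late. Ribosomal protein genes were among them, as 58 rose and 0 fell of 58 (58 and 0 adjusted over the list alone). The median was 1.25 (camera adjusted p = 4.26e-27, adjusted p = 0.229 with an estimated correlation). For stress response genes 23 rose and 1 fell of 25 (23 and 2 adjusted over the list alone). The median was 1.09 (camera adjusted p = 3.28e-11, adjusted p = 0.205 with an estimated correlation). For cholesterol synthesis genes 17 rose and 0 fell of 19 (17 and 0 adjusted over the list alone). Their median was 1.22 (camera adjusted p = 7.84e-08, adjusted p = 0.229 with an estimated correlation). For mesenchyme markers 21 rose and 2 fell of 23 (21 and 2 adjusted over the list alone). The list median was 1.69 (camera adjusted p = 5.36e-08, adjusted p = 0.229 with an estimated correlation). For leukocyte markers 20 rose and 3 fell of 24 (20 and 3 adjusted over the list alone). The median was 1.42 (camera adjusted p = 5.46e-07, adjusted p = 0.259 with an estimated correlation). For mitochondrially encoded genes 5 rose and 0 fell of 5 (5 and 0 adjusted over the list alone). The median was 1.53 (camera adjusted p = 3.90e-05, adjusted p = 0.116 with an estimated correlation).

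For melanocyte markers 7 rose and 0 fell of 8 (7 and 0 adjusted over the list alone). Members had a median of 1.14 (camera adjusted p = 9.86e-05, adjusted p = 0.0930 with an estimated correlation). For matrix remodelling genes 22 rose and 4 fell of 31 (22 and 4 adjusted over the list alone). Their median was 0.84 (camera adjusted p = 3.07e-05, adjusted p = 0.142 with an estimated correlation). For inflammation genes 18 rose and 2 fell of 27 (18 and 2 adjusted over the list alone). The set had median 0.77 (camera adjusted p = 0.000117, adjusted p = 0.229 with an estimated correlation). For muscle markers 7 rose and 0 fell of 10 (7 and 0 adjusted over the list alone). The median was 0.56 (camera adjusted p = 0.00374, adjusted p = 0.123 with an estimated correlation). For glycolysis and hypoxia genes 18 rose and 5 fell of 30 (18 and 5 adjusted over the list alone). Their median was 0.37 (camera adjusted p = 0.00164, adjusted p = 0.600 with an estimated correlation). The muscle list lost its call with no filter (adjusted p = 0.0510). In 2 lists genes were lower late. Supporting cell genes fell, as 2 rose and 13 fell of 16 (2 and 13 adjusted over the list alone). Across the list the median was -1.44 (camera adjusted p = 8.72e-06, adjusted p = 0.0930 with an estimated correlation). DNA replication genes fell, as 1 rose and 14 fell of 28 (1 and 14 adjusted over the list alone). The median was -0.29 (camera adjusted p = 0.0168, adjusted p = 0.604 with an estimated correlation). This call ended with narrower windows (adjusted p = 0.273) and without 24 and 168 h (adjusted p = 0.239).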
